A study of Rattus norvegicus with 4 samples.

How the data were processed

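Each of the 4 mammary cancers was measured on 1 array. Per the labels' protocols, total RNA was extracted with acid guanidine phenol and chloroform, cleaned on a silica membrane, and 8 µg was reverse transcribed from an oligo-dT primer carrying a T7 promoter and labelled with biotin by in vitro transcription. Priming at the poly(A) tail favours the 3' end of transcripts. The series' design text names 1 group of 4 cancers matched with another series, and that series is not analysed here.

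The deposited table holds linear intensity values, 1 for each of 31099 probe sets per tumour, in the form the authors gave. The software, background correction and scaling are not given in the sources used here. The values themselves show that the arrays had been brought to a common level, since the mean after trimming 2% from each end was 500.1 on all 4. The median signal was 221.9, 203.3, 201.8 and 219.2 in tumours 1 to 4, and the highest values lay between 12739 and 17928. The number of arrays limits the precision, and no detection call or saturation flag was used here. No 2 arrays held identical values.

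Intensities were transformed as log2(value + 16), and each array was shifted to a common median by -0.07, 0.05, 0.06 and -0.05. The largest difference between these shifts was 0.13 log2. After this shift the median expressed gene lay at -0.13, 0.10, 0.11 and -0.08 relative to the mean of the other tumours. Part of this offset came from the shift itself. Shifts of gene lists were therefore judged against those of random lists, and a shift given without a random value cannot be read by its sign alone. Random lists matched to the luminal list lay at -0.24 in tumour 1, and at -0.15 with the values as deposited. Probe sets were named from a probe table of the platform annotation. It covered 21268 probe sets, of which 436 named several genes and were left out, and 20826 named 1 gene and were used. Control probe sets were left out, and 9831 probe sets had no entry and are unnamed here. The gene identifiers of 20764 probe sets were found in the RefSeq gene table of assembly GRCr8, and no symbol changed. Of several probe sets for a gene, the one with the highest mean was used, which gave 14217 genes. The 9403 genes whose mean reached the median of all probe-set means (7.81 log2, a signal of about 209) are called expressed. The unnamed probe sets include 2790 at that level, of which 84 (3.01%) had a 4-fold range. Genome coordinates are not given because the labels and the deposited files name no build.

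Since all samples form 1 group without technical replicates, no significance test was run. Differences were described by rules of size and by random lists. Genes with a 4-fold range differ by at least 2 log2 between the highest and the lowest tumour. A gene is apart in a tumour when it lies at least 1 log2 above or below each of the other 3. Pearson and Spearman correlations were computed across genes. For each gene list, the median SD of its members and, per tumour, the median difference from the mean of the other 3 tumours (the shift) were set among 10000 random lists of equal size matched on mean level in 20 bins. A value outside the central 95% is described as outside the random range, which is a description of these arrays and not a p-value. Lists needed at least 5 expressed genes. By construction about 5% of 100 list and tumour pairs fall outside by chance if genes are independent, and 49 did. The pairs are not separate outcomes, because a low value in 1 tumour raises the shifts of the others and some lists share genes. The count of 49 therefore overstates the excess.

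The 32 lists covered cell types (luminal, hormone-responsive, basal, fibroblast, endothelial, adipocyte, brown adipocyte, skeletal muscle, epidermal, lymphoid, myeloid, mast cell and red blood cell genes) and genes of other organs as background. They also covered milk proteins, proliferation, antigen presentation and interferon response, p53 targets, DNA repair, oncogenes, growth factors, lipid synthesis and oxidation, prostaglandins, hypoxia, immediate early genes, endoplasmic reticulum stress, epithelial-mesenchymal transition, ribosomal proteins and oxidative phosphorylation. Of 749 distinct list genes, 97 had no named probe set. The lists, the tests, the alternatives and the rule for naming genes were set before the data were examined. That rule named the 10 genes of largest SD, and for each tumour the 3 genes furthest above and the 3 furthest below by the gap to the nearest tumour. It also named the 4 members of largest SD in each list outside the random range for spread and the 4 members furthest in the direction of each shift outside it. Finally it named 25 anchor genes, of which 23 had a named probe set and 20 were expressed. The text gives a selection of the genes so named. Gaps of other tumours and ranges beside them come from the same probe sets. The decision to describe in full the 16 shifts of at least 0.5 log2 was made after the values were seen, as were the look at probe sets of the RT1 family, the listing of genes in unscored lists, and the separate recalculation of smaller shifts.

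Counts, correlations, list spreads, shifts and named genes were recomputed with quantile normalization, with no shift between arrays, with a shift to the 75th percentile, without the expression filter, with a filter at the 75th percentile, with the mean of all probe sets of a gene, with pseudocounts of 1 and 64, with 5 bins for the random lists (spreads and shifts only), and without each tumour in turn. The values of RT1 probe sets, of unnamed probe sets and of genes in unscored lists were not recomputed. The procedure was tested on simulated data for the 9403 genes with known answers. It found apart 95% of 100 genes raised by 1.5 log2 and 100% of 100 genes raised by 3 log2 in simulated tumour 2, and 0% of unraised genes. A proliferation list raised by 0.5 log2 was found outside the random range, as were 7.29% of unshifted list and tumour pairs, against 5% by design. Gene SDs in the simulation were capped at the median SD, so these rates are optimistic for variable genes. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.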

Results

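Transcript levels were measured on 1-colour oligonucleotide arrays in 4 mammary cancers that arose in female Sprague-Dawley rats, an outbred stock, after carbon-ion irradiation. The rats received 1 whole-body dose of 0.5 Gy at 7 weeks of age and, from an age of 9 weeks, ate a high-fat diet in which corn oil made up 23.5%. Carbon ions are a densely ionising radiation used in radiotherapy, and the beam here had an energy of 290 MeV/u and a spread-out Bragg peak, the depth range over which the dose is delivered, of 6 cm. All 4 cancers belong to 1 group, each was measured on 1 array, and the labels do not say whether the 4 tumours came from separate rats. Tumours from unirradiated rats and normal mammary gland are not analysed here, so no value below measures an effect of irradiation or diet. The comparison that the design allows is between the individual tumours, and it asks how far carbon-ion mammary cancers differ from one another. With 1 array per tumour no difference has a replicate check, so no p-value is given. Values are log2 signal with a pseudocount of 16, and a difference of 1 on this scale is 2-fold for well expressed genes and understates the change of weakly expressed ones.

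The 4 cancers shared most of their transcript profile, and a minority of genes differed by at least 2-fold between the highest and the lowest tumour. Among 9403 expressed genes, 1224 had such a 2-fold range, 226 (2.40%) a 4-fold range and 18 a 16-fold range. The median standard deviation (SD) between tumours was 0.23 log2, the 90th percentile was 0.50, and 804 genes had an SD under 0.1. Tumours 2 and 3 were the closest pair, with a Pearson correlation across genes of 0.955 and 214 genes at least 2-fold apart. Tumours 1 and 3 were the furthest pair by that correlation, at 0.893 with 658 such genes, and the correlations of tumour 1 with tumours 2 and 4 were 0.906 and 0.895. Genes are not independent replicates, so these correlations describe the arrays only. Tumour 1 had 205 genes at least 2-fold above or below each of the other tumours, tumour 4 had 92, tumour 3 had 44 and tumour 2 had 33. Leaving out tumour 1 lowered the number of genes with a 4-fold range from 226 to 98, and leaving out tumour 4 lowered it to 146.

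Separate probe sets of 1 gene gave a measure of error at the level of probes, but not of the RNA, labelling or array, which they share. In 2330 genes with at least 2 expressed probe sets, the same tumour was highest on both of the brightest probe sets in 49.3% of genes. Chance gives 25% if each tumour is equally often highest, and more if, as the offsets between arrays imply, it is not. The contrast between highest and lowest tumour reached at least 2 log2 on the brightest probe set of 33 of these genes. The next probe set changed in the same direction in 33 of the 33, and in 32 it showed at least 50% of the contrast. At a contrast of at least 1 log2 the direction was shared in 213 of 226 genes. Such a check was not made for 193 of the 226 genes with a 4-fold range, which had only 1 expressed probe set. Probe sets under the expression filter were left out of it, so the agreement holds for genes whose second probe set is bright. Some probe sets under the filter did not share the pattern, as for Fcrla, Igf2 and Sv2b below, while that of Ptgs1 did.

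**Figure D1:**
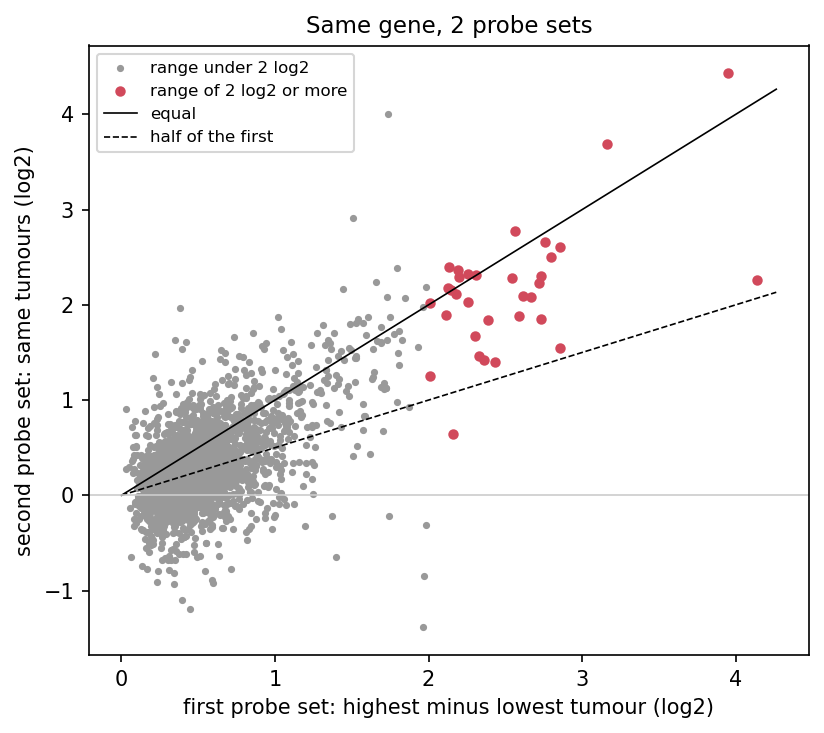
Each point is a gene with at least 2 expressed probe sets; the horizontal axis gives the difference in log2 signal between its highest and lowest tumour on the brightest probe set, and the vertical axis gives the difference between the same tumours on the next probe set. Red points are the 33 genes with a difference of at least 2 log2 on the brightest probe set, of which 32 lie above the dashed line that marks 50% of that difference.

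The 10 genes of largest SD between tumours included several genes of milk. Glycam1, a mucin secreted into milk, measured 11.86, 12.15, 13.44 and 7.20 log2 in tumours 1 to 4. Csn2, which encodes beta-casein, lay between 13.26 and 13.91 in tumours 1 to 3 and at 8.76 in tumour 4. Sncg, gamma-synuclein, followed the same pattern, with 11.60 to 12.25 in tumours 1 to 3 and 7.17 in tumour 4. Glycam1 and Sncg were under the level of the expression filter in tumour 4, so the size of their differences is uncertain. Lpo, the milk enzyme lactoperoxidase, and Pigr, the receptor that carries polymeric immunoglobulin across epithelium into milk, were high in tumour 1 only, at 11.57 and 12.57 against at most 7.60 and 8.58 elsewhere. The B-cell gene Fcrla also peaked in tumour 1, at 13.06 against at most 8.97, but its other probe set stayed between 5.53 and 6.35 in all 4 tumours, so the value is uncertain. Some of these genes split the tumours in pairs. Jchain, the joining chain of polymeric immunoglobulins, was at 10.88 and 10.70 in tumours 1 and 4 and at 7.44 and 6.74 in tumours 2 and 3. Thbs4, a matrix thrombospondin, was at 11.44 and 11.49 in tumours 1 and 3 and at 7.33 and 6.61 in tumours 2 and 4. Aadat, an aminotransferase of the kynurenine pathway, was at 12.39 and 10.68 in tumours 2 and 3 and at 7.00 and 7.83 in tumours 1 and 4. Cemip2, a cell-surface hyaluronidase, had the largest SD of all, 2.87, with 6.21 and 6.60 in tumours 1 and 2 and 10.74 and 11.87 in tumours 3 and 4. The lower pairs of values of Jchain, Thbs4 and Cemip2 were under the filter level, as were Aadat in tumour 1 and Lpo outside tumour 1. The sizes of these differences are uncertain too.

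**Figure D2:**
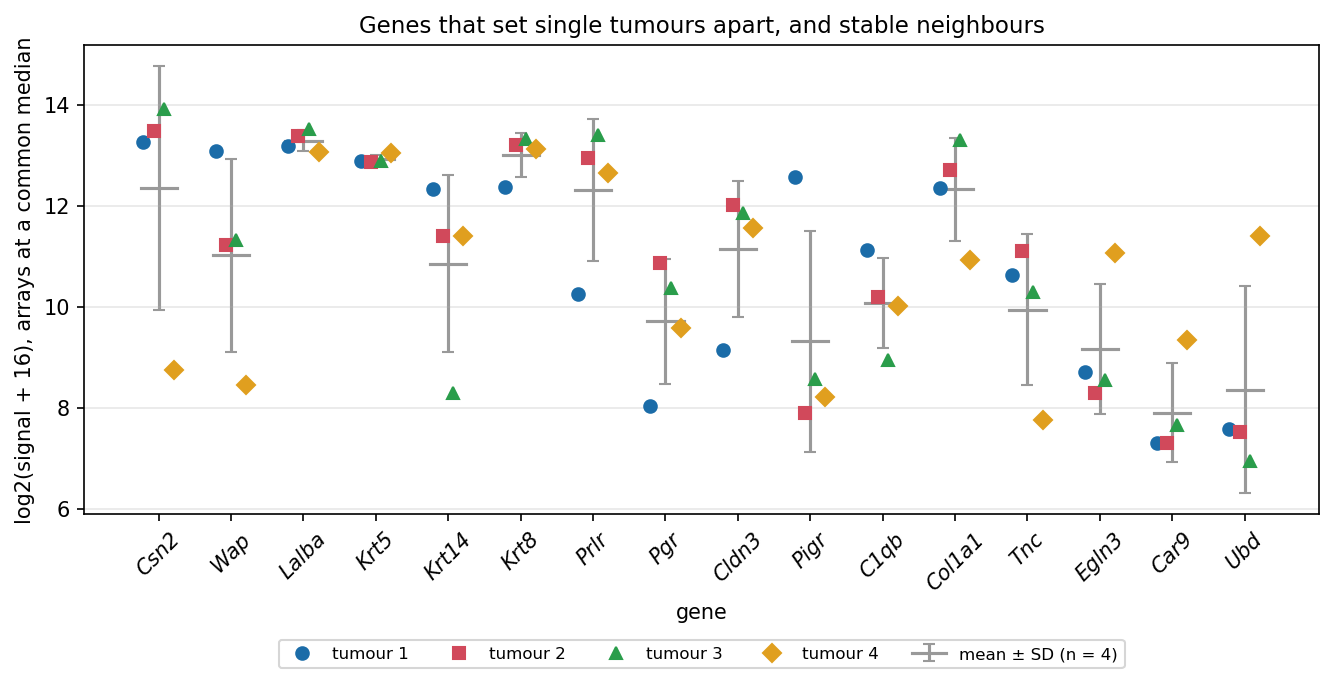
Log2 signal (vertical axis) of 16 genes in each of the 4 tumours, with the grey bars giving the mean and SD over the 4 tumours (n = 4). Csn2 and Wap are lowest in tumour 4 and Prlr and Pgr in tumour 1, whereas Krt5 (12.92 ± 0.08) and Lalba (13.29 ± 0.21) hardly vary. Both lie near the upper end of the signal range, where arrays lose contrast.

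Of 32 gene lists fixed beforehand, 25 had enough expressed members to be set against random lists of matched expression level. The members of 17 lists varied more between tumours than the central 95% of random lists, and no list varied less. The hormone-responsive epithelial list (10 genes) varied most, with a median SD of 0.86 against 0.23 in random lists, followed by the fibroblast and collagen matrix list (24 genes) with 0.84 against 0.22. Macrophage and myeloid genes, growth factors with the ligands of the epidermal growth factor receptor, and genes of epithelial-mesenchymal transition each had a median SD of 0.56, and prostaglandin genes one of 0.53. The 11 further lists above the random range had a median SD between 0.33 and 0.49. They were antigen presentation by major histocompatibility complex (MHC) class II, endothelium, adipocyte, luminal epithelium, milk proteins, hypoxia and glycolysis, MHC class I with the interferon response, mammary oncogenes and tumour suppressors, basal and myoepithelial genes, proliferation, and fatty acid oxidation. Several of these calls rested on 1 tumour. Without tumour 1 the median SD was 0.20 for the luminal list, 0.24 for adipocyte genes, 0.23 for MHC class I, 0.19 for oncogenes and 0.22 for fatty acid oxidation, all within the range of random lists. The proliferation list fell within that range without tumour 2 (0.18), the MHC class II list without tumour 3 (0.27), and the hypoxia and milk protein lists without tumour 4 (0.22 and 0.29). Adipocyte genes (0.33) also came inside it without tumour 2, fatty acid oxidation (0.30) without tumour 3, and prostaglandin genes without tumour 2 or tumour 4 (0.23 and 0.26). The endothelial list did so without tumour 2, 3 or 4 (0.36, 0.35 and 0.29), and when the probe sets of a gene were averaged (0.31). Restricting the genes to the brighter 25% of probe sets brought the milk protein (0.30), oncogene (0.27) and prostaglandin lists (0.34) inside the range, and removing the expression filter did so for fatty acid oxidation (0.30). Random lists treat genes as independent, so a list whose members are expressed together leaves their range more readily than its size alone would give.

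**Figure D3:**
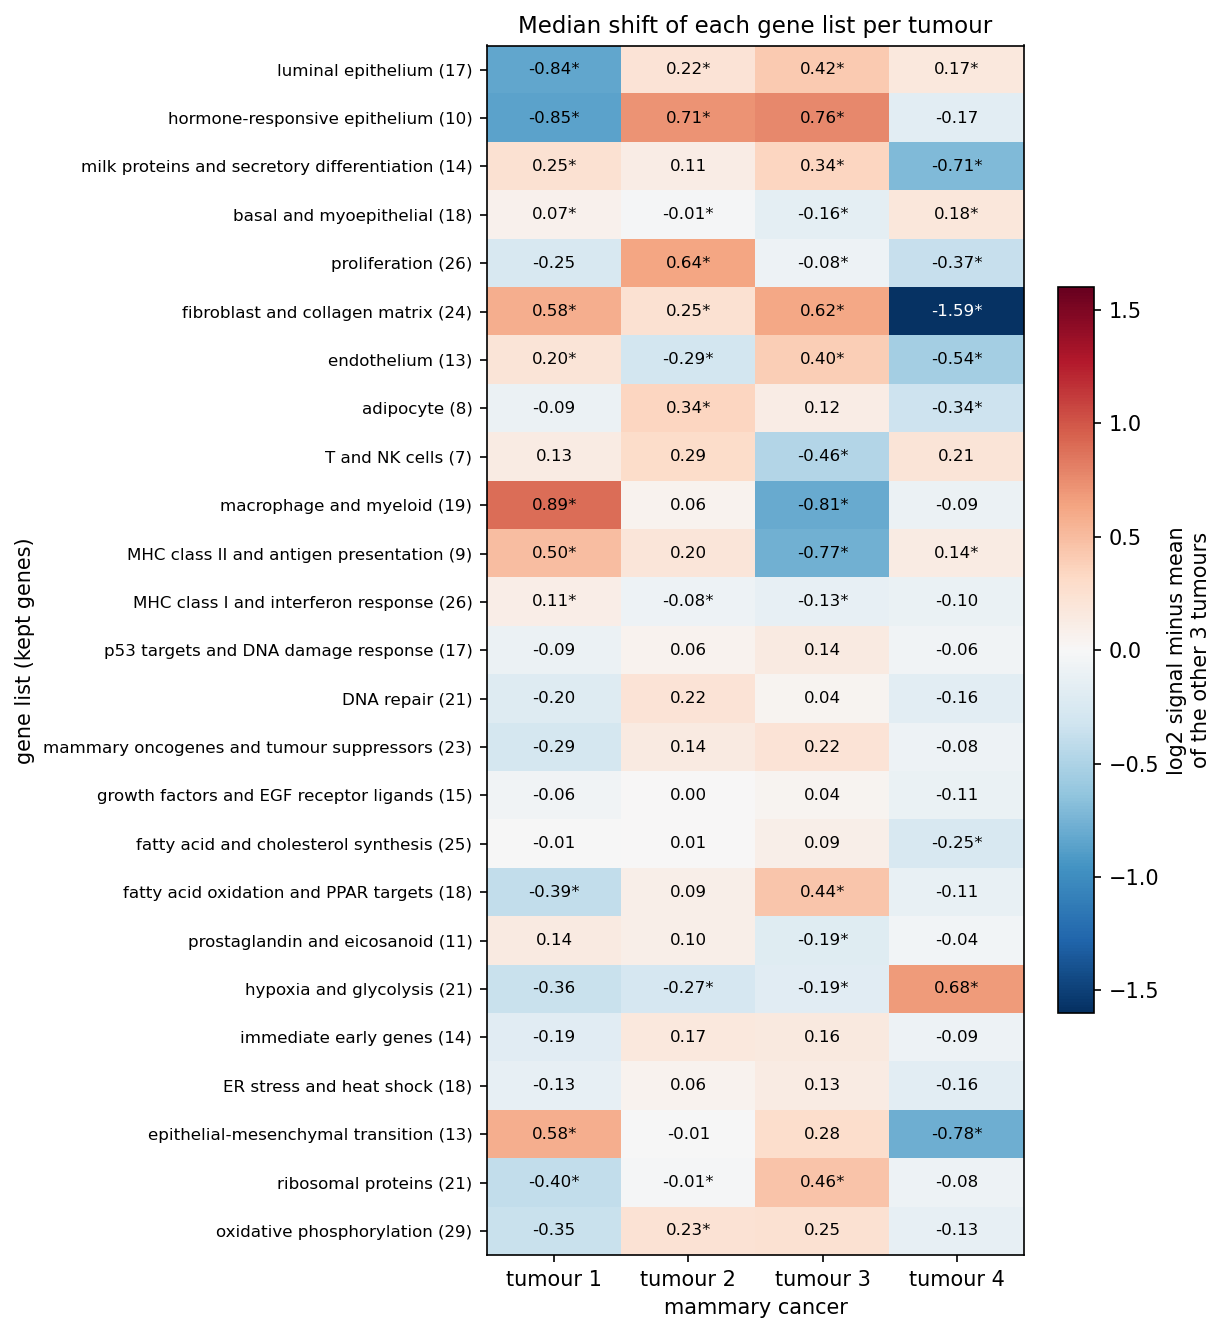
Median over each gene list (rows, with the number of expressed members) of the log2 signal in 1 tumour minus the mean of the other 3 tumours (columns and colour). An asterisk marks a shift outside the central 95% of 10000 random lists matched on expression level, whose own median is not 0; the fibroblast and collagen matrix list in tumour 4 (-1.59) is the largest shift.

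Tumour 1 had lower transcripts of luminal and hormone-responsive epithelium and higher macrophage transcripts than the other 3 cancers. Of 17 luminal genes, 16 were below the mean of the other tumours, 15 were lowest in tumour 1, and the median shift was -0.84 log2 against -0.24 in random lists. Prlr, the prolactin receptor, was at 10.25 against 12.65 to 13.41, with all 3 of its probe sets lowest in this tumour. The tight-junction gene Cldn3 was at 9.15 against 11.56 to 12.02. The keratin gene Krt7 and Gata3, a transcription factor of luminal cells, differed from the mean of the others by -1.42 and -1.26. Of 10 hormone-responsive genes, 8 were below the mean of the others, and the median shift was -0.85 against -0.20. Pgr, the progesterone receptor, was at 8.04 against 9.57 to 10.87. Wnt4, which acts downstream of progesterone, differed by -2.07, and Areg, a ligand of the epidermal growth factor receptor, by -1.98. Prlr and Gata3 belong to both lists. The luminal list was above the random range in tumours 2, 3 and 4, with shifts of 0.22, 0.42 and 0.17, but without tumour 1 these became -0.09, 0.15 and -0.14, of which the first was below the random range and the others inside it. Without tumour 3 the values in tumours 2 and 4 were 0.41 and 0.35. With all tumours, the value in tumour 2 was at the edge of the random range and came inside it with probe sets averaged, a pseudocount of 1 or 5 bins for the random lists. With only the brighter 25% of probe sets the hormone-responsive shift was -1.62. Basal and myoepithelial genes did not fall with the luminal genes, with 9 of 18 above the mean of the others in tumour 1 and a shift of 0.07 against -0.19 in random lists. That shift was 0.18 without tumour 3, 0.15 without tumour 4 and 0.30 after quantile normalization, but -0.08, inside the random range, with the brighter 25% of probe sets.

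All 19 macrophage and myeloid genes were above the mean of the other tumours in tumour 1, 16 were highest there, and the median shift was 0.89 against -0.14 in random lists. The integrin gene Itgax exceeded the mean of the others by 1.44, the complement genes C1qb and C1qc by 1.40 and 1.27, and the inhibitory Fc receptor gene Fcgr2b by 1.27. MHC class II genes shifted by 0.50 against -0.18 in random lists, and 8 of 9 were highest in tumour 1. This shift was 0.26, still outside the random range, without tumour 3. The list of MHC class I and interferon genes did not move as one, with a median of 0.11, 14 genes above the mean of the others and 12 below it. The 4 genes furthest above were the antiviral genes Mx1, Ifit2, Rsad2 and Mx2, by 2.42, 2.20, 2.16 and 1.67. The other probe set of Mx2, under the expression filter, stayed between 6.40 and 6.52. Isg15, another interferon-induced gene, was at 11.04 against 10.08 to 10.18. Genes of epithelial-mesenchymal transition shifted by 0.58, with 9 of 13 above the mean of the others, among them the transcription factor genes Zeb2 (1.44) and Twist1 (1.09). That shift was 0.29 without tumour 4. The genes furthest below all other tumours were Wfdc2, a secreted protease inhibitor (9.24 against 11.95 to 12.10), the receptor tyrosine kinase Ret (6.82 against 9.51 to 10.77) and the angiotensin receptor Agtr1a (8.93 against 11.44 to 11.68). Both probe sets of Agtr1a and all 3 of Ret were lowest in tumour 1. Ret was under the filter level there, so the size of its difference is uncertain. Control probe sets for RNA integrity did not set tumour 1 apart, with log2 ratios of 3' over 5' signal of 0.03 for GAPDH (-0.02 to 0.04 elsewhere) and 0.30 for beta-actin (0.30 to 0.48 elsewhere).

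Tumour 2 had higher transcripts of the cell cycle. All 26 proliferation genes were above the mean of the other tumours, 23 were highest in tumour 2, and the median shift was 0.64 log2 against 0.09 in random lists. The mitotic checkpoint kinase gene Bub1 and the cyclin genes Ccna2 and Ccnb2 exceeded the mean of the others by 1.04, 1.01 and 0.92. Mki67, which encodes the Ki-67 antigen, was at 10.42 against 9.54 to 10.02. The differences were moderate, and 2 of the 26 genes reached 2-fold. All 29 oxidative phosphorylation genes were above the mean of the others too, by a median of 0.23 against 0.12 in random lists, with 27 above it after quantile normalization. This shift was 0.15 without tumour 1 and 0.37 without tumour 3. Hormone-responsive genes shifted by 0.71, led by Pgr (1.55) and the oestrogen-regulated gene Greb1 (1.12), whose other probe set, under the expression filter, was highest in tumour 1. This value depended on the tumours it was set against, with 0.11 without tumour 1, inside the random range, 1.11 without tumour 3, and 0.46 with weakly expressed genes included. Adipocyte genes shifted by 0.34, or by -0.07, inside the random range, with only the brighter 25% of probe sets, with Cfd, the adipokine adipsin, at 9.28 against 7.68 to 8.11. Ramp3, a partner of calcitonin-family receptors, the carboxypeptidase-like gene Cpxm1 and the growth factor gene Igf2 were furthest above the other tumours, at 11.51, 10.83 and 11.72 against at most 9.28, 8.69 and 9.93. The other 3 probe sets of Igf2 stayed between 4.41 and 5.21 in all tumours. The metalloproteinase Mmp7, complement C3 and the ciliary transport gene Ift27 were furthest below, at 6.32, 8.39 and 6.72, and their gaps to the nearest tumour were -2.24, -2.13 and -1.48. Mmp7 and Ift27 were under the filter level in tumour 2, so the size of their gaps is uncertain. Hpgd, which inactivates prostaglandins, was at 9.85 against 8.05 to 8.34, and its other probe set was also highest in tumour 2.

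Tumour 3 had the lowest macrophage and antigen-presentation transcripts. Of 19 macrophage and myeloid genes, 18 were below the mean of the other tumours, 16 were lowest in tumour 3, and the median shift was -0.81 log2 against 0.12 in random lists. It was -0.53 without tumour 1, where these genes were high. The secreted phosphoprotein gene Spp1 differed from the mean of the others by -1.77, and C1qb and C1qa by -1.49 and -1.28. Aif1 differed by -1.40, but its other probe set was at 8.22 in tumour 3 against 7.83 to 8.41 elsewhere. All 9 MHC class II genes were below the mean of the others, and the median shift was -0.77 against 0.16. Cd74, the invariant chain, was at 11.70 against 12.80 to 13.11, and RT1-Db1 and RT1-Da differed by -1.27 and -0.83. RT1-Bb showed the largest difference, -2.72, although its probe sets disagree between tumours. The pan-leukocyte gene Ptprc was at 7.96 against 8.77 to 9.64, and the T and natural killer cell list (7 genes) shifted by -0.46, or by -0.29 without tumour 1. Among basal genes, Krt14, the basal keratin, was at 8.30 against 11.39 to 12.33, while its partner Krt5 was at 12.89 against 12.87 to 13.04. Krt5 lies near the upper end of the signal range, where arrays lose contrast, so differences in it may be understated. The basal list as a whole shifted by -0.16 against 0.16 in random lists, or by -0.08 without tumour 1 and -0.31 without tumour 2, and 12 of 18 genes were below the mean of the others. Tp63, a master regulator of basal cells, was at 9.96 against 10.80 to 11.40.

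Hormone-responsive genes shifted by 0.76 in tumour 3, by 0.41 without tumour 1 and by 1.20 without tumour 2, with the chemokine gene Cxcl14 at 13.13 against 10.79 to 11.69. Fatty acid oxidation genes shifted by 0.44 against 0.12 in random lists, with 17 of 18 above the mean of the others. The carnitine transferase gene Cpt1a exceeded that mean by 0.66, and Angptl4, a target of peroxisome proliferator-activated receptors, by 1.12. The same list shifted by -0.39 in tumour 1, where Acaa2, a mitochondrial thiolase, was at 9.61 against 11.12 to 11.60. Collagen matrix genes shifted by 0.62 in tumour 3 and by 0.58 in tumour 1, against 0.17 and -0.20 in random lists. Both values were set by the low level in tumour 4. Without tumour 4 the shifts were 0.07, inside the random range, and 0.03, and without tumour 3 the shift in tumour 1 was 0.98. In tumour 2 the same list shifted by 0.25, by 0.48 without tumour 1 and by 0.49 without tumour 3, but by -0.20, below the random range, without tumour 4. The genes furthest above the other tumours were Rprm, a p53-inducible cell cycle inhibitor (10.22 against at most 7.86), the forkhead gene Foxd2 (9.59 against at most 7.81) and the synaptic vesicle gene Sv2b (11.44 against at most 9.71). The other 2 probe sets of Sv2b did not share this pattern. Besides Krt14, the salivary secretory protein gene Csap1 (8.72 against at least 10.92) and the protease inhibitor Serpinb1a (8.79 against at least 10.78) were furthest below, and the other Serpinb1a probe set was lowest in tumour 3 as well.

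Tumour 4 had lower collagen matrix and milk protein transcripts and higher transcripts of the hypoxia response. All 24 fibroblast and collagen matrix genes were below the mean of the other tumours, 23 were lowest in tumour 4, 18 were at least 2-fold below that mean, and the median shift was -1.59 log2 against -0.09 in random lists. Col1a1 and Col1a2, which encode the chains of type I collagen, were at 10.93 and 10.70 against at least 12.36 and 12.58, and both probe sets of each gene were lowest in tumour 4. The matrix glycoprotein gene Tnc differed from the mean of the others by -2.91, the fibroblast receptor gene Pdgfra by -2.41 and Col6a1 by -2.01. The epithelial-mesenchymal list, which shares Fn1 and Sparc with the collagen list, shifted by -0.78, with 10 of 13 genes below the mean of the others. That value was -0.49 with weakly expressed genes included and -0.32 with only the brighter 25% of probe sets. Its members did not move as one, since Twist1 differed by -1.58 and the collagenase gene Mmp13 by 2.19. Endothelial genes shifted by -0.54, with 8 of 13 below the mean of the others, and by -0.35 when all probe sets of a gene were averaged. The receptor gene Tek was at 7.40 against 8.12 to 8.64, and Plvap, a gene of fenestrated endothelium, differed by -0.86. Adipocyte genes shifted by -0.34, or by -0.24, inside the random range, without tumour 1 and by -0.26, also inside it, with only the brighter 25% of probe sets. Macrophage genes shifted by -0.09, inside the random range. Luminal genes shifted by 0.17 against -0.10 in random lists, or by -0.14, inside the random range, without tumour 1. Basal and myoepithelial genes shifted by 0.18 against -0.09 in random lists, with 15 of 18 above the mean of the others.

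Of 14 milk protein and secretory genes, 13 were below the mean of the others in tumour 4, 10 were lowest there, and the median shift was -0.71 against -0.09 in random lists. It was -0.43 without tumour 1 and -0.28 with only the brighter 25% of probe sets. Glycam1, Csn2 and Wap differed by -5.29, -4.80 and -3.43. Glycam1 was under the filter level in tumour 4, so the size of its difference is uncertain. Lpo differed by -3.10, a value set mostly by its high level in tumour 1, and was under the filter level in tumours 2 to 4. Wap, the whey acidic protein, was at 8.45 against 11.21 to 13.08. Of the 14 genes, 6 were at least 2-fold below the mean of the others, but some of the rest hardly differed. Csn1s1, which encodes alpha-S1-casein, was at 13.38 against 13.34 to 14.05, and Lalba, alpha-lactalbumin, at 13.06 against 13.18 to 13.52, both close to the upper end of the signal range, where arrays lose contrast. Csn2 was near that end in tumours 1 to 3, so its difference is subject to the same limit. The milk list shifted by 0.25 in tumour 1 and 0.34 in tumour 3, against -0.21 and 0.19 in random lists. Without tumour 4 the shifts were -0.11 and 0.13, both inside the random range. The value in tumour 3 also came inside it after quantile normalization (0.10), without tumour 2 (0.41), with a pseudocount of 1 (0.35), without the expression filter (0.31) and with the brighter 25% of probe sets (0.40). Without tumour 1 it was 0.53, outside it. Among 21 hypoxia and glycolysis genes, 19 were above the mean of the others, 16 were highest in tumour 4, and the median shift was 0.68 against -0.09. The list shifted by -0.27 in tumour 2 and by -0.19 in tumour 3, or by -0.13 and 0.06 without tumour 4, the latter inside the random range. The value in tumour 2 was -0.45 without tumour 3, and that in tumour 3 was -0.37 without tumour 2. The oxygen sensor gene Egln3 was at 11.07 against 8.30 to 8.70, carbonic anhydrase Car9 at 9.34 against 7.29 to 7.66, the mitophagy gene Bnip3 at 11.53 against 10.01 to 10.03, and the glucose transporter gene Slc2a1 at 11.38 against 10.27 to 10.49. Furthest above the other tumours were Ubd, a ubiquitin-like modifier (11.39 against at most 7.57), the medium-chain acyl-CoA synthetase gene Acsm3 (10.70 against at most 7.58) and the MHC class I gene RT1-CE10 (12.80 against at most 9.82). RT1-CE10 belongs to a family of near-identical paralogs, so its value is uncertain. Car9, Ubd and Acsm3 were under the filter level in the other tumours, so the size of their differences is uncertain. Ptgs1, the constitutive cyclooxygenase, was at 10.52 against 7.70 to 8.18, and its other probe set was highest in tumour 4 too. Thrsp, a regulator of lipogenesis, was at 9.98 against 11.54 to 12.54, with all 3 probe sets lowest in tumour 4, and the proliferation list shifted by -0.37, or by -0.14 without tumour 2, inside the random range.

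Among the 25 lists, those of DNA repair and of p53 targets had the 2 lowest median SDs. The 17 p53 targets had a median SD of 0.21 and the 21 DNA repair genes one of 0.19, against 0.22 and 0.24 in random lists, and neither list shifted outside the random range in any tumour. Cdkn1a, the p53-induced cell cycle inhibitor, was at 10.20 ± 0.31 (mean ± SD, n = 4 tumours) and Mdm2, the p53 ubiquitin ligase, at 10.50 ± 0.14. Endoplasmic reticulum stress genes (median SD 0.21) and immediate early genes (0.29) also stayed within the random range. Fatty acid and cholesterol synthesis genes did so as well (0.28), although this list shifted by -0.25 in tumour 4, or by -0.19, inside the range, without tumour 1. Fasn, fatty acid synthase, was at 12.65 ± 0.22 on its brightest probe set, but its other probe set ran from 12.80 and 12.37 in tumours 1 and 2 to 11.07 and 11.20 in tumours 3 and 4. Scd, a desaturase, was at 8.81 ± 0.38. The T and natural killer cell list (0.35) and oxidative phosphorylation genes (0.27) were within the range for spread too. Growth factors and oncogenes varied more than random lists, but neither list shifted outside the random range in any tumour, except that oncogenes did in tumour 3 after quantile normalization (0.13). The members of largest SD were Igf2 (1.23), Areg (1.01), the connective tissue growth factor gene Ccn2 (0.70) and the ligand gene Btc (0.68) in the first list. In the second they were the cell cycle inhibitor Cdkn2a (0.79), Notch4 (0.65), Wnt1 (0.58) and Fgfr2 (0.56). Erbb2 was at 9.77 ± 0.36, Egfr at 10.75 ± 0.21, Ccnd1, cyclin D1, at 12.59 ± 0.33 and Myc at 10.81 ± 0.51. The oestrogen receptor gene Esr1 (6.78 ± 1.40), the inducible cyclooxygenase Ptgs2 (5.22 ± 0.89) and the adipocyte gene Adipoq (6.59 ± 0.48) had means under the expression filter, where signal and background are hard to part. With an SD of 1.40, Esr1 was not at 1 level in the 4 tumours, and its low mean does not show that it was at background in each.

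The ribosomal protein list (21 genes, median SD 0.26, within the random range) was lowest in tumour 1 in all 21 genes and highest in tumour 3 in all 21, with shifts of -0.40 and 0.46 log2. Random lists of equally bright genes shifted by -0.30 and 0.27 in the same tumours, and after quantile normalization the shifts of the ribosomal list were -0.03 and 0.01, both inside the random range. The ribosomal shift in tumour 1 also came inside it without tumour 3 (-0.25), without tumour 4 (-0.47) and with the brighter 25% of probe sets (-0.40). Without tumour 2 it was -0.43, outside the range. The prostaglandin list shifted by -0.19 in tumour 3, against 0.10 in random lists. It shifted by 0.06 without tumour 1, -0.03 without tumour 2, -0.08 without the expression filter and 0.15 with the brighter 25% of probe sets, all inside the random range. Without tumour 4 it was -0.38, outside it. Ptgds, a prostaglandin D synthase, was at 7.93 there against 8.98 to 10.85.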

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

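The results in this part have 1 tumour that stands far from the other 3, judged by its gap to the nearest tumour relative to the whole range. Among 4 values chance alone singles out about 1 in 20, and all of the tests of explanations in this part were chosen after the results were seen. Of 10 measures of array quality 2 were singled out (0.5 expected by chance) and of 25 gene lists 2 (1.2 expected). Of 156 named genes 14 were singled out, and of 24 genes picked by this same gap 6. Most of the 156 were named for a large spread or for standing with 1 tumour's shift, so no chance level applies to either count of genes.

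The array of tumour 1 differed most from the mean of the others, with a median absolute difference 0.071 log2 larger than that of the next array. The 3' over 5' ratio of beta-actin was 0.171 log2 higher in tumour 3 than in the next tumour. Spiked bacterial and phage controls had a mean log2 signal of 10.01, 10.16, 10.34 and 9.58 in tumours 1 to 4. They were lowest in tumour 4, though not singled out by this rule, and what this means for the values of tumour 4 was not tested. Among genes picked by their gap, Pigr lay 3.99 log2 above and Wfdc2 and Agtr1a lay at -2.71 and -2.51 from the nearest other tumour in tumour 1. In tumour 4, Ubd lay 3.82 above and Csn2 and Sncg at -4.50 and -4.44. Sncg was under the level of the expression filter there, and Ubd was under it in the other tumours. In tumour 1 the epithelial junction genes Cldn3, Cldn7 and Cdh1 had gaps of -2.41, -0.87 and -0.74, and Cebpa and the interferon-induced Isg15 had gaps of 0.84 and 0.86. In tumour 2, Ccnb2 and Hpgd were set off by 0.86 and 1.52, and Gbp2 by -0.66. In tumour 4, Ptgs1, Egln3 and Bnip3 had gaps of 2.34, 2.37 and 1.49, and Krt5 one of only 0.149. Col1a2 and Col6a3 had gaps of -1.88 and -1.89 in tumour 4, although the other probe set of Col6a3 was lowest in tumour 2. Of the lists, the median of the collagen matrix genes, each centred on its mean, lay at -1.37 from the nearest other tumour in tumour 4, and that of the hypoxia list 0.65 above it.

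For the lower luminal list in tumour 1, a lower share of epithelial cells was considered. With expression per cell unchanged, it would also pull down milk transcripts, which are epithelial too. The milk protein list shifted by 0.25 in tumour 1 and the basal list by 0.07, against -0.21 and -0.19 in random lists. The milk list shifted by -0.11 without tumour 4, where the luminal shift was -0.81, and the lower quartiles of the milk list were above the luminal shift both ways. Some milk transcripts lie near the top of the signal range, which limits this test. The differences of the 14 milk genes in tumour 1 also varied widely, with an SD of 1.48 log2. Bulk RNA does not part cell share from expression per cell, so the milk list cannot decide whether the epithelial share was lower. Scaling between arrays is argued against by the luminal shift of -0.66 after quantile normalization, still outside the random range, and RNA degradation by the 3' over 5' ratios, of which 0 of 3 were highest in tumour 1. A lower share of luminal cells and a lower luminal programme within the tumour cells both stay open, as hypotheses that the labels do not allow to be tested.

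The lower collagen list in tumour 4 does not go with an equally lower share of all non-epithelial cells, since the macrophage list shifted by -0.0923 there, inside the random range. Endothelial and adipocyte genes were low along with it, at -0.54 and -0.34, so a lower share of part of the stroma stays open. Scaling between arrays is also argued against, because the shift was -1.54 after quantile normalization. A lower share of fibroblasts and lower expression per fibroblast cannot be told apart in bulk RNA, as both would put most of the 24 genes low, and 18 were at least 2-fold below the mean of the others. Beyond cell shares and joint MHC transcription, no biological explanation was tested for these patterns, since the design gives a single group.

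Of 29 probe sets of the RT1 family, the rat MHC, that reached the filter level in at least 1 tumour, 5 were at least 2-fold higher in tumour 4 than in every other tumour (63 of 13747 among all named probe sets at that level). In tumour 3, 3 were at least 2-fold lower than in every other (66 of 13747), and 2 of these were probe sets of 1 gene, RT1-Db1. Higher in tumour 4 were RT1-Ba probe sets at 11.85 and 12.03 against at most 6.78, while another RT1-Ba probe set was lowest in tumour 4, at 10.17. Sequence differences under the probe sets may account for this in an outbred stock, and in 2 of 5 RT1 genes (40%) the probe sets disagreed by at least 2 log2 in tumour 4, against 5 of 2682 other genes (0.186%), but with 5 genes, seen before the test was set, this stays open. Higher transcription of MHC genes as a set would lift the whole MHC class II list, which shifted by only 0.14 in tumour 4, above the random range but with an upper quartile of 0.32. Without tumour 3 that shift was -0.14, inside the range, and without tumour 1 it was 0.41, all far under the gaps of these probe sets. The class II list cannot test the class I probe sets among them, those of RT1-CE10 and RT1-CE16. It also takes only the brightest probe set of a gene, which for RT1-Ba was the one lowest in tumour 4.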

How the results depend on the processing

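No paired analysis was possible because all samples form 1 group. Of 191 recalculated shifts of at least 0.5 log2, 189 kept their sign and stayed outside the random range and 2 came inside it. Size was not part of this count, and some shifts that kept their call became small. The collagen shift in tumour 1 ranged from 0.03 to 0.98 over the settings, and the milk protein shift in tumour 4 from -0.81 to -0.28. Of 323 recalculated list spreads 290 kept their call, 21 came inside the range and 12 left it. Of 2424 recalculations of named genes 2240 moved by less than 1 SD and 184 by more. Most of these concerned the range of a gene, which has no direction and cannot reverse. Direction was followed only for the 24 genes picked by their gap, and none of those reversed. Shifts under 0.5 log2 were less stable, with 14 of 33 keeping their call whichever tumour was left out. With other filters, averaged probe sets, other pseudocounts or 5 bins, 179 of 198 recalculations of these kept their call, 15 came inside the random range and 4 could not be scored. Of the 15, 7 came from the stricter filter. Under quantile normalization 4 of the 49 shifts outside the random range came inside it, 3 of them of the ribosomal list. Others left the range, namely oxidative phosphorylation in tumour 1 (-0.19), fatty acid and cholesterol synthesis in tumour 2 (-0.09) and oncogenes in tumour 3 (0.13). Where a value below changed its call, the cause was not tested, apart from the number of genes or tumours that the setting itself removes. Weak signals limit the lower end, where the median SD was 0.29 under 8 log2 against 0.21 between 10 and 11.

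Without the expression filter there were 563 genes with a 4-fold range, the lowest correlation between arrays was 0.947, probe sets shared the highest tumour in 43.4% of genes, and 427, 127, 217 and 233 genes were apart in tumours 1 to 4. The spread of fatty acid oxidation was 0.297. With the stricter filter these numbers were 97 genes, 0.845, 53.3%, and 92, 12, 22 and 40 genes apart, and the spreads of milk proteins, oncogenes and prostaglandin genes were 0.297, 0.269 and 0.338. The endothelial and the T and NK cell lists had too few genes left there to be scored. With probe sets averaged, the endothelial spread was 0.310.

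Leaving out 1 tumour at a time gave 98 to 193 genes with a 4-fold range, a lowest correlation of 0.891 to 0.933 and 50.4% to 58.0% of genes with a shared highest tumour. Chance alone gives a higher share when fewer tumours remain than in the full set. These percentages therefore cannot be set directly beside the 49.3% of the full set. Genes apart numbered 261 to 343 in tumour 1, 58 to 92 in tumour 2, 78 to 126 in tumour 3 and 136 to 156 in tumour 4, as fewer tumours remain to lie apart from. List spreads ranged from 0.197 to 0.510 for luminal genes, 0.243 to 0.514 for adipocyte, 0.228 to 0.461 for MHC class I, 0.269 to 0.598 for MHC class II, 0.190 to 0.375 for oncogenes and 0.221 to 0.364 for fatty acid oxidation. They ranged from 0.180 to 0.405 for proliferation, 0.292 to 0.458 for endothelium, 0.225 to 0.513 for prostaglandin genes, 0.293 to 0.503 for milk proteins and 0.219 to 0.479 for hypoxia. The hormone-responsive shift in tumour 2 ranged from 0.107 to 1.11 and the collagen shift in tumour 3 from 0.0739 to 0.928.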

Other observations

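Genes of lists too small to be scored were looked at after the data were seen. The beta-globin gene Hbb was at 12.94 log2 in tumour 4 against 10.27 to 11.38 in the others, and the alpha-globin gene Hba-a3 at 9.81 against 6.76 to 8.35. Of the red blood cell list, 2 of 8 measured genes were expressed. Among B and plasma cell genes, Jchain was high in tumours 1 and 4, on both of its probe sets (9.53 and 10.10 on the other, against 7.27 and 7.35), and Cd22 lay between 8.41 and 9.10. Of the epidermal list, Krt15, a basal keratin, was at 12.99, 12.44, 11.86 and 12.56 in tumours 1 to 4, and Calml3, a calmodulin-like gene of stratified epithelium, at 10.58, 8.94, 8.76 and 9.59. Among mast cell genes, Cpa3 lay between 7.81 and 8.91, Tpsb2 between 8.16 and 9.14, and the receptor gene Kit, which luminal progenitor cells also use, between 10.22 and 11.32.

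Signs of adjoining tissue were few. Of 25 skeletal muscle genes measured, 3 were expressed, and of 20 adipocyte genes 8 were. The muscle myosin gene Myh1 was at 12.34 to 12.53 in all 4 tumours (SD 0.08) while most muscle genes were under the filter, so its signal alone cannot be read as muscle. A second expressed probe set of Myh1 differed by 0.12 between the tumours that were highest and lowest on the first. Tnni2 and Atp2a1 lay at or below 8.77. Of the brown adipocyte list only Cidea passed, at 7.63 to 8.22. Among 29 genes of other organs 2 passed the filter, namely Ins1, at 7.59 to 8.09, and Gfap, a glial filament gene, 2.69 log2 higher in tumour 1 than in any other tumour, where it lay at 6.89 to 7.32.

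Fam111a, a nuclear protease gene chosen after its values were seen, split the tumours into pairs as Jchain and Thbs4 do, with 12.12 and 11.44 in tumours 2 and 3 and 9.00 and 8.50 in tumours 1 and 4.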
